A study of Homo sapiens with 6 samples.

How the data were processed

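Gene expression was measured in 2 human lung cancer cell lines, HCC95 and H460, on Illumina HumanHT-12 v4 beadchips, per the labels' protocols. HCC95 cells carried a GFP control vector or an LZTFL1 vector and were untreated or treated with TGFβ. H460 cells carried either vector and were untreated. Each of the 6 groups had 1 array, and the group of each array was taken from its label.

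The authors deposited a table of probe signal intensities that were not normalized, with a detection p-value beside each intensity. They also deposited a table of processed intensities on a linear scale. GenomeStudio version 2011.1 is named for both, per the submitters' processing notes, and its settings are not given in the sources used here. The deposited detection p-values moved in steps of 1 in 770. The processed columns had a median of 13.1 and a lowest value of 3.33, and each ranked its probes as the signal of its own array did (rank correlation 1). The same quantiles in every column and the low minimum were read as quantile normalization and background correction by the authors; the method is not given in the sources used here and stays unknown.

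The signal intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function estimated the background from the detection p-values, corrected it with normexp, added an offset of 16, quantile-normalized the arrays and took log2. The offset draws small values together, so a fold of a dim gene is understated. Of 47323 probes, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17202 were not listed there. Of the probes with 1 symbol, 30074 were matched by gene identifier to the reference gene table, which updated old symbols. The 20046 named genes were each represented by the probe with the highest mean over the 6 arrays. Probes without a listed gene were kept as features of their own, counted and not named.

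A gene entered a pair of arrays if its detection p was under 0.01 on at least 1 of them. A value that was not detected was raised to the lowest value among the detected probes of its array if it lay below that. Such a difference is a bound and is written as "at least". If the undetected array then came out the higher of the pair, the difference was set to 0, and such zeros enter the list medians of the pairs. No p-value was computed for a single pair, because there was no replicate. Genes with a difference of 2-fold or more, 1 on the log2 scale, were counted. The spread between probes of a gene was taken from genes with more than 1 detected probe.

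Additive limma models were fitted across arrays with eBayes and a mean-variance trend, with Benjamini-Hochberg adjustment at 0.05, over genes detected on at least 2 of the arrays fitted. The LZTFL1 effect shared by the 3 contexts used all 6 arrays with context as a block, which left 2 residual degrees of freedom. The TGFβ effect used the 4 HCC95 arrays with vector as a term, and the cell line difference used the 4 untreated arrays with vector as a term. Each of these left 1 residual degree of freedom. The LZTFL1 fit was also made on the 4 HCC95 arrays, without the H460 pair; this count was chosen before the data were examined, and its list tests and recounts after. In these fits the difference between contexts is the error. Nothing in the labels says that cultures were replicated, so the p-values do not measure a spread between cultures. The number of arrays limits the precision. With 1 or 2 residual degrees of freedom, eBayes takes much of a gene's SE from other genes of like brightness. An SE or p-value below is therefore not that gene's own spread between arrays. LTB had TGFβ effects of 1.94 with GFP and 4.03 with LZTFL1, yet an SE of 0.255 in the TGFβ fit.

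The fits were tested on simulated data, with 200 genes changed. Each changed gene was shifted by the same amount in every context, with independent noise at the variances that the fits had estimated. The recovery therefore checks the calculation and does not measure power for real effects, which may differ between contexts. Of 100 genes changed by 1 on the log2 scale, the shared LZTFL1 fit over 14101 genes recovered 95, the TGFβ fit over 12735 genes recovered 89 and the cell line fit over 13803 genes recovered 90. All 100 genes changed by 2 were recovered in each, with 9, 2 and 13 false calls.

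Before the data were examined, 18 gene lists were fixed, covering mesenchymal, epithelial, basal, lung secretory, motile cilia, BBSome and intraflagellar transport, Hedgehog, MAPK output, TGF-β target, cell cycle, interferon, NF-κB, unfolded protein and amino acid stress, hypoxia, cholesterol, NRF2 and housekeeping genes, and markers of stromal, endothelial and white blood cells. In a single pair, a list's median difference was ranked among 10000 random lists of the same size matched on brightness in 10 bins. In the fits, lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The second form has only the 1 or 2 residual degrees of freedom of the fit, too few to tell whether a list moved. The genes to be named were also fixed then. They were LZTFL1, the 6 highest and 6 lowest differences of each pair, the 3 highest and 3 lowest bounds, and the genes called in the shared LZTFL1 fit. The rule added the 10 highest and 10 lowest genes moving alike in all pairs of a contrast, the 5 highest and 5 lowest for the difference between TGFβ effects and the 8 highest and 8 lowest for the cell lines. Members of each list with a difference of at least 1 were named, or up to 4 with the largest. Members past a fit's threshold are also given, and this choice was made after their values were seen.

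The gene counts of the pairs, of the difference between TGFβ effects and of the fits above were recomputed under other normalizations. These were no background correction (log2 of the signal plus 16, quantile-normalized), an offset of 50, median scaling in place of quantile normalization, and the authors' deposited processed intensities after a floor of 16. The counts were also recomputed without the detection filter, with detection on every array, and with the mean of a gene's detected probes. No such recount is given for the fit of an LZTFL1 effect that differs between lines. Pairs were counted at 1.5-fold as well. The fits were repeated without the context or vector term and without the trend, and the shared LZTFL1 fit with each pair of arrays left out. The position of each array on its slide was not used here, so slide could not be a block.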

Results

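RNA from HCC95 and H460 cells was profiled on 6 arrays, 1 for each group, so no value below has a replicate within its group. HCC95 is an established line derived from a squamous lung cancer and H460 one derived from a large cell lung cancer. LZTFL1 is a leucine zipper protein that regulates traffic of the BBSome, a carrier of cilium proteins. The design asked what an LZTFL1 vector does to expression in both lines and, in HCC95, what it does with and without TGFβ, with epithelial differentiation and MAPK and Hedgehog signalling as the stated interest. Median probe signals lay between 104 and 125. The numbers of detected probes were 16067 for HCC95 with GFP, 16423 for HCC95 with LZTFL1, 14715 for H460 with GFP and 16038 for H460 with LZTFL1. The arrays labelled TGFβ had the fewest, 14136 with GFP and 14232 with LZTFL1. Correlations across probes were 0.982 to 0.987 among HCC95 arrays, 0.989 for the H460 arrays and 0.906 to 0.911 between lines.

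LZTFL1 itself was read by 1 probe (ILMN_1815705), whose position relative to the introduced sequence is not known here, so that it may not read the vector's transcript. Its normalized log2 value was 5.75 in HCC95 with GFP and 5.07 in HCC95 labelled LZTFL1. In the arrays labelled TGFβ it was 5.40 with GFP and 5.07 with LZTFL1, and in H460 it was 6.36 and 6.39. The probe was detected at p under 0.01 in HCC95 with GFP (0.0026) and in both H460 arrays (0.0013 and 0). In H460 the array labelled LZTFL1 was higher by 0.03, less than the spread between probes of a gene in that pair (0.199), and in HCC95 the arrays labelled LZTFL1 were not detected, so these arrays are named below by their labels.

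In untreated HCC95, the largest differences between the array labelled LZTFL1 and the GFP control were genes lower with LZTFL1. MMP10, a secreted matrix metalloproteinase, was 19.7-fold lower (log2 -4.30), and the cytokine IL1A was 6.74-fold lower (-2.75). LTB, which encodes lymphotoxin beta, differed by -2.66, AMTN, which encodes amelotin, by -2.49 and IGFBP3, which binds insulin-like growth factors, by -2.27. A probe annotated to the MIR21 locus differed by -2.00. On the array labelled LZTFL1, LTB (5.50) and the MIR21 probe (5.51) lay near its lowest detected value (5.33). Higher genes were SCNN1A, the alpha subunit of the epithelial sodium channel, by 1.86, SLC39A7 by 1.75, SPP1, which encodes osteopontin, by 1.65, CEMIP by 1.61, CHGB by 1.54 and the peroxiredoxin PRDX4 2.83-fold. Another probe of SLC39A7 differed by only 0.33, another of SPP1 by 1.53 and another of IGFBP3 by -1.11. Among genes detected on 1 array, FBN2 was at least 2.69-fold higher and LCP1 at least 2.62-fold lower. In all, 61 of 14342 genes were at least 2-fold higher and 86 at least 2-fold lower. With median scaling in place of quantile normalization the split was 30 higher and 209 lower.

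Between the HCC95 arrays labelled TGFβ, the one labelled LZTFL1 again had MMP10 lower, by at least 21.6-fold (log2 -4.43, not detected with LZTFL1). The cadherin CDH11 differed by -1.97, the cytochrome P450 gene CYP1A1 by -1.95, the tight junction gene CLDN1 by -1.93, the MIR21 probe by -1.93, ANXA10 by -1.79 and IGFBP3 by -1.77. SCNN1A was higher by 2.10, SERPINA3, which encodes a secreted protease inhibitor, by 1.56, the kinetochore gene SPC24 by 1.56, S100P by 1.51, LGALS1 by 1.45 and SPP1 by 1.44, against 0.51 for another SPP1 probe. After MMP10, the bounds lower were led by STOM, at least 3.55-fold lower with another probe at -0.64, and DAPL1, at least 3.02-fold lower. Here 52 of 12443 genes were at least 2-fold higher and 105 at least 2-fold lower. The differences of the untreated and TGFβ-labelled pairs, which share no array, correlated across 10800 genes with r = 0.488, although genes are not independent replicates. Of the genes past 2-fold in both pairs, 20 were higher in both (0.253 from independent lists), 39 lower in both (0.720 from independent lists) and 0 went opposite ways. The labels do not say that the vector cells of each pair were made separately. A lasting difference between a GFP and an LZTFL1 cell population would give the same agreement. The agreement therefore does not show that LZTFL1 was the cause.

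Fitted over the 4 HCC95 arrays, 972 of 12735 genes passed the threshold with limma at 1 residual degree of freedom. Of these, 476 rose and 496 fell with the LZTFL1 label, or 110 and 290 with median scaling. MMP10 fell by 4.46 on the log2 scale (SE 0.164, adjusted p = 1.79e-17), with 1 of its 4 values not detected, IL1A fell by 2.13, and SCNN1A rose by 1.98. The count was 86 without the mean-variance trend and 5 without the treatment term, so it rests on both.

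The list of unfolded protein and amino acid stress genes fell in this fit: 10 of 18 measured members fell, 1 rose and 7 did not pass (12 fell and 1 rose when adjusted over the list alone; camera adjusted p = 7.22e-09; adjusted p = 0.716 with an estimated correlation). The test with an estimated correlation has 1 residual degree of freedom here, so it cannot tell whether a list moved. CHAC1, which degrades glutathione, fell by 1.51. VLDLR, a lipoprotein receptor, changed by -1.08, the secreted hormone gene STC2 by -0.96 and CTH, an enzyme of cysteine synthesis, by -0.92, while SDF2L1, an endoplasmic reticulum chaperone partner, rose by 0.42. Of 20 basal and squamous genes, 8 fell and 0 rose (10 adjusted over the list alone; adjusted p = 1.19e-06; adjusted p = 0.716 with an estimated correlation). KRT14, a keratin of basal cells, fell 3.03-fold, and the desmosome cadherins DSG3 and DSC3 changed by -1.04 and -0.82. Of 15 mesenchymal genes, 4 fell and 0 rose (4 adjusted over the list alone; adjusted p = 0.0260; adjusted p = 0.716 with an estimated correlation). They were CDH11 (-1.72), the matrix gene TNC (-1.70), CDH2, which encodes N-cadherin (-1.65), and the repressor SNAI2 (-0.69).

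Genes that report MAPK pathway output rose: 5 of 18 rose, 0 fell and 13 did not pass (9 rose and 2 fell adjusted over the list alone; adjusted p = 0.0260; adjusted p = 0.716 with an estimated correlation). These were the transcription factor ETV4 (0.74), the feedback regulators SPRY2 (0.69) and SPRED2 (0.52), CCND1, which encodes cyclin D1 (0.51), and IER3 (0.50). Lung secretory genes rose by the same test, with 2 of 7 members called (2 adjusted over the list alone; adjusted p = 0.0299; adjusted p = 0.716 with an estimated correlation), the transcription factors FOXA2 (1.19) and CEBPA (0.57). Of 27 cell cycle genes, 3 rose and 0 fell (3 adjusted over the list alone; adjusted p = 0.0323; adjusted p = 0.753 with an estimated correlation), led by BIRC5 (0.76). Over all genes 972 of 12735 were called. Another BIRC5 probe differed by -0.14 in the untreated pair and by 0.29 in the TGFβ-labelled pair, so its rise was not shared by both probes. Hedgehog genes did not pass (adjusted p = 0.338): of 7 measured, GLI2, a transcription factor of the pathway, fell by 0.50 and 6 did not pass. The epithelial list did not move as a whole (adjusted p = 0.830), because 4 of 21 members rose, led by RAB25 (1.05), and 3 fell, led by CLDN1 (-1.93) and the desmosome gene DSP (-1.03).

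The other lists did not pass the list test in this fit. Adjusted p was 0.0601 for BBSome and intraflagellar transport genes with 0 of 20 called, and 0.830 for motile cilia genes with 0 of 4 called. For TGF-β targets it was 0.0934 with 2 of 19 higher and 4 lower, led by THBS1 (-1.17). It was 0.140 for NF-κB genes with 1 of 12 higher, LCN2 (1.12), and 3 lower. Interferon (0.495), hypoxia (0.830), cholesterol (0.286), NRF2 (0.830) and housekeeping genes (0.0580) did not pass either. Of 13 NRF2 targets, 3 rose and 4 fell, so members moved both ways although the list did not shift in 1 direction. Of 10 housekeeping genes, 2 fell and 0 rose. The housekeeping median was -0.17 (percentile 3.52) in the untreated pair and -0.20 (percentile 1.6) in the TGFβ-labelled pair. Of 10 interferon genes 1 rose, and of 13 cholesterol genes 2 rose. Of 15 hypoxia genes, 1 rose and 1 fell. Of 3 measured markers of other cell types, THY1 fell by 1.09 and 2 did not pass (adjusted p of the list = 0.209).

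**Figure D1:**
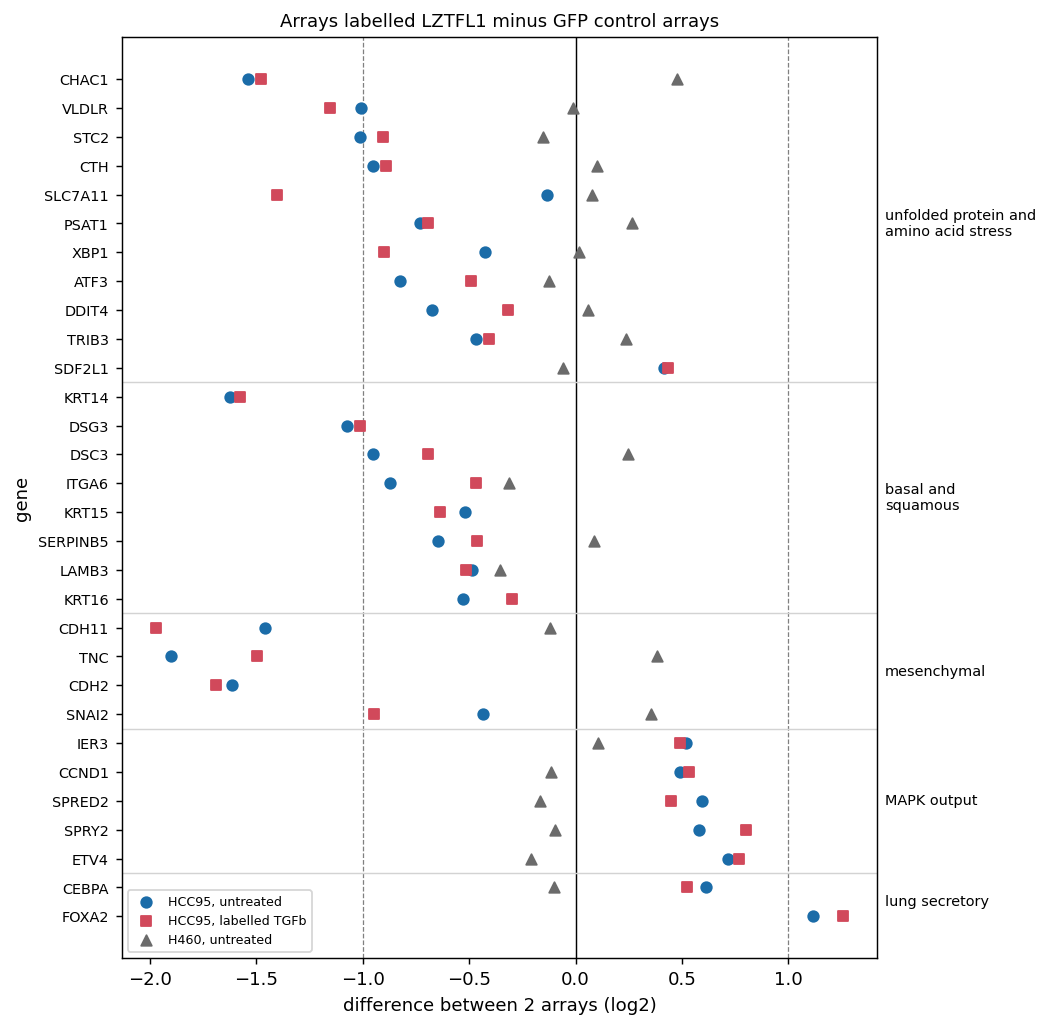
The horizontal axis is the log2 difference between an array labelled LZTFL1 and its GFP control, and each row is a member of a fixed list that passed the 4-array HCC95 fit. Circles are untreated HCC95, squares HCC95 labelled TGFβ and triangles H460, each 1 array against 1, with undetected values raised to the detection floor and dashed lines at 2-fold; the circle and square of KRT14 lie at -1.62 and -1.58, and H460 has no point for a gene detected on neither of its arrays.

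In H460, differences between the array labelled LZTFL1 and its control were small. Among genes detected on both arrays, the largest rises were those of PIGV, a gene of GPI anchor synthesis, by 1.29, and SCARNA16, a small Cajal body RNA, by 1.00. CFI was higher by 0.97, TPCN2 by 0.93, STX3 by 0.85 and LHFPL2 by 0.85. VOPP1 differed by -1.29, TELO2 by -1.13, SLX1B, which has a near-identical copy, by -1.10, GSN, which encodes gelsolin, by -1.07, IGFBP5 by -1.04 and DNAAF9 by -0.98. On the array labelled LZTFL1, VOPP1 (5.39), GSN (5.38) and IGFBP5 (5.39) lay at its lowest detected value (5.38). None of the genes with a second detected probe was past 2-fold in this pair. Among genes detected on 1 array, FOSL2 was higher by at least 1.06 and KLK10 differed by at least -1.14. All 13 measured cholesterol and fatty acid synthesis genes were lower, with a median of -0.22 that lay below 10000 random lists (percentile 0). Among them, HMGCS1 differed by -0.32 and FASN by -0.30. The basal list had a median of -0.31 (percentile 0) over 9 genes, of which 3 were higher, and its mean was -0.15. The Hedgehog median was 0.09 (percentile 87.6) and the MAPK median 0.02 (percentile 69.9).

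The H460 count was 11 of 13589 genes at least 2-fold higher and 10 lower, or 16 and 3 with median scaling and 38 and 103 with the processed values. Different probes of a gene agreed less here than in HCC95, with r = 0.156 across genes against 0.505 in untreated HCC95, and the H460 differences did not correlate with those of either HCC95 pair (r = 0.00598 and -0.0658).

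Across both lines and all 3 contexts, 1 gene passed the limma fit of a shared LZTFL1 effect, SCNN1A, which rose by 1.66 (SE 0.196, adjusted p = 0.0475). It was not called without background correction, with an offset of 50, with the processed values, with averaged probes, without the trend or without the context term. It was not detected on every array, and in H460 its difference at the detection floor was 0.14. The fit took the undetected H460 value as it stood, below that floor, so the 1.66 rests in part on background signal. At an unadjusted p under 0.05 there were 1394 of 14101 genes, but 1601 with only the H460 vector labels exchanged. The 10 genes that led those higher in all 3 pairs were the small Cajal body RNAs SCARNA16 (1.09 in the fit, adjusted p = 0.0632), SCARNA8 (0.99) and SCARNA14 (0.79), the elongation factor gene ELL3 (0.73, not detected on every array), the near-identical U1 variants RNVU1-7 (0.89) and RNVU1-18 (0.83), TEDC2 (0.90), SNORD56 (0.51), MIR1185-1 (0.52) and SNORD38A (0.87, not detected on every array). Those lower in all 3 were led by SOCS2, an inhibitor of cytokine signalling (2.00-fold lower), RNF19A (-0.76), DNAAF9 (-0.74), ZNF589 (-0.63) and FOXQ1 (-0.84). None of these passed the threshold. The unfolded protein list (adjusted p = 5.64e-06) and the basal list (adjusted p = 1.08e-05) fell in this fit as lists, with 0 members called over all genes and 6 and 4 adjusted over the list alone; adjusted p = 0.653 with an estimated correlation for both. The fall of the unfolded protein list was in HCC95, since in H460 its median was 0.00 (percentile 53.2), with 9 members above 0 and 9 below. The LZTFL1 effect differed between H460 and HCC95 for 43 genes in a limma fit with that term.

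TGFβ, transforming growth factor beta, is a cytokine that acts through SMAD proteins. In HCC95, the arrays labelled TGFβ were higher for inflammatory genes and lower for several textbook TGF-β targets than the untreated arrays. The chemokine CCL20 rose by 2.46 (5.49-fold, SE 0.184, adjusted p = 5.38e-10), IL1B by 2.38, LTB by 2.99, and GDF15 by 1.90. PLEK and the chemokine CCL2 also rose but were not detected on every array, and CCL2 was higher by at least 1.69 with GFP and at least 1.65 with LZTFL1. PMEPA1, a TGF-β target that restrains SMAD signalling, fell by 2.77 (6.83-fold, SE 0.195, adjusted p = 1.81e-10), and CRYAB, a small heat shock protein, fell by 2.74. LYPD1 also fell, by at least 1.80 in the LZTFL1 pair, where it was not detected with TGFβ and another probe differed by -0.57. FST, which encodes the activin antagonist follistatin, changed by -1.49, RDH16 by -1.36 and PTPRK by -1.20. These directions go against the label for the targets, so the arrays are named by their labels only.

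With GFP, the highest differences of the array labelled TGFβ were CYP1A1 (2.26), CCL20 (2.20) and IL1B (2.14), and the lowest CRYAB (-2.52), PMEPA1 (-2.22) and AMTN (-2.20). With LZTFL1, the highest were LTB (4.03), CCL20 (2.71) and IL1B (2.61), and the lowest PMEPA1 (-3.32), CRYAB (-2.96) and FST (-1.93). Another probe of PMEPA1 differed by -2.16 with GFP and -2.56 with LZTFL1. Another of LTB, not detected on the untreated arrays, differed by 2.04 and 2.36. The counts at 2-fold were 87 higher and 32 lower of 13386 genes with GFP, and 132 higher and 76 lower of 13769 with LZTFL1. With median scaling they were 26 and 242 with GFP, and 82 and 144 with LZTFL1. These pairs share no array, and their differences correlated across 10800 genes with r = 0.489; 47 genes were past 2-fold higher in both (0.823 from independent lists), 9 lower in both (0.195 from independent lists) and 1 went opposite ways.

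The TGFβ fit called 786 of 12735 genes, 435 higher and 351 lower. With median scaling it called 121 higher and 746 lower, with the median of all genes at -0.21. Without the trend it called 55 and without the vector term 9.

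Of 12 measured NF-κB and inflammatory genes, 7 rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 6.92e-12; adjusted p = 0.542 with an estimated correlation). Beside CCL20 and IL1B these were IL1A (1.49), CXCL8 (1.35), IL6 (1.31), LCN2 (0.92) and NFKBIA (0.82). Of 13 NRF2 targets, which defend against oxidation, 7 rose and 0 fell (10 adjusted over the list alone; adjusted p = 3.07e-07; adjusted p = 0.542 with an estimated correlation), led by PGD (0.87), AKR1B10 (0.73) and TXNRD1 (0.58). Of 18 unfolded protein and amino acid stress genes, 4 rose, STC2 (0.45), DDIT4 (0.45), TRIB3 (0.43) and ASNS (0.37), and 0 fell (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.00390; adjusted p = 0.542 with an estimated correlation). With median scaling the median of this list in the GFP pair turned to -0.17 from 0.17. The 3 measured markers of other cell types all rose (3 adjusted over the list alone; adjusted p = 3.99e-05; adjusted p = 0.542 with an estimated correlation): VWF, a clotting factor of endothelium, 3.04-fold, the lysosomal protein CD68 by 0.80 and the surface protein THY1 by 0.78.

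TGF-β targets fell: 8 of 19 fell, 0 rose and 11 did not pass (9 fell and 1 rose adjusted over the list alone; adjusted p = 0.00353; adjusted p = 0.542 with an estimated correlation). Beside PMEPA1 these were the matrix protein THBS1 (-1.07), the SMAD corepressor SKIL, TPM1 (-0.86), the inhibitory SMAD7 (-0.70), ITGA2 (-0.66), CDKN1A (-0.59) and BHLHE40 (-0.50). The pair medians were 0.00 with GFP (percentile 54.1, mean -0.23) and -0.10 with LZTFL1 (percentile 9.38, mean -0.43), so the fall rests on part of the list. Of 15 mesenchymal genes, 4 fell, SNAI2 (-1.10), CDH2 (-0.91), CDH11 (-0.65) and TNC (-0.63), and S100A4 rose by 0.99 (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.0163; adjusted p = 0.542 with an estimated correlation). Of 20 basal genes, 5 fell, led by S100A2 (-0.82), and KRT13 rose (8 fell and 3 rose adjusted over the list alone; adjusted p = 0.0135; adjusted p = 0.542 with an estimated correlation). Of 27 cell cycle genes, 4 fell and 0 rose (7 adjusted over the list alone; adjusted p = 3.99e-05; adjusted p = 0.542 with an estimated correlation), RRM2 (-0.89), CDK1 (-0.57), FOXM1 (-0.54) and TYMS (-0.54).

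The other lists did not pass in the TGFβ fit. Adjusted p was 0.962 for epithelial genes, although CLDN1 rose by 1.14 and ELF3 by 1.02, and the median (-0.08) and mean (0.06) of that list differed in sign. It was 0.131 for lung secretory, MAPK output and cholesterol genes, 0.261 for interferon, hypoxia and housekeeping genes, 0.328 for Hedgehog, 0.434 for BBSome and intraflagellar transport and 0.979 for motile cilia genes. Of 15 hypoxia genes, 4 rose and 1 fell.

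**Figure D2:**
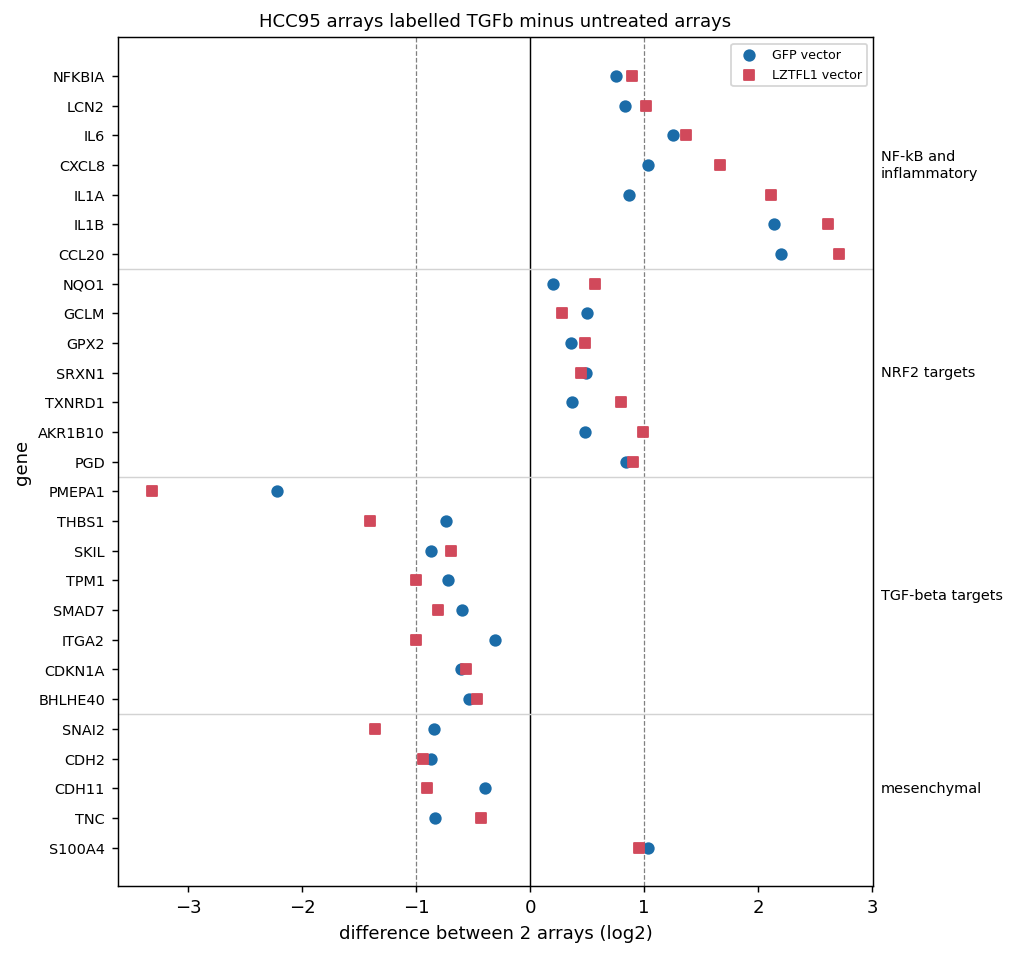
The horizontal axis is the log2 difference between an HCC95 array labelled TGFβ and the untreated array with the same vector, and each row is a member of a fixed list that passed the TGFβ fit. Circles are the GFP vector and squares the LZTFL1 vector, each 1 array against 1, with undetected values raised to the detection floor and dashed lines at 2-fold; PMEPA1 lies at -2.22 and -3.32 and CCL20 at 2.20 and 2.71.

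Whether the LZTFL1 vector changed the response was read as the difference of both TGFβ effects, without a test. LTB had a TGFβ effect that was higher with LZTFL1, by 2.09 on the log2 scale, but by 1.21 when its probes were averaged. On the untreated arrays LTB was 5.50 with LZTFL1, near the lowest detected value of that array (5.33), against 8.16 with GFP. On the arrays labelled TGFβ it was 9.54 with LZTFL1 and 10.10 with GFP. Its other probe rose by 2.04 with GFP and 2.36 with LZTFL1. That probe was not detected on either untreated array, so it cannot show whether the vectors differed there. LTB was followed by AKAP8L (1.71) and PIM1, a kinase gene (1.55). The chemokine CXCL14 (-1.46), MOCS2 (-1.52), ORMDL2 (-1.43) and B3GNT2 (-1.43) had TGFβ effects that were lower with LZTFL1, and for B3GNT2 they were -1.41 with LZTFL1 against 0.02 with GFP. AMTN (1.58), GSTTP2 (1.49) and NDUFB1 (-1.59) involved undetected values, and GSTTP2 turned to -0.25 when its probes were averaged. Of 14675 genes, 96 were at least 2-fold higher and 84 lower, or 296 and 33 with median scaling. There is no replicate check on these differences.

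Between the untreated arrays, H460 and HCC95 differed in 7345 of 13803 genes, 3468 higher in H460 and 3877 higher in HCC95. H460 was higher for S100A4 by 8.15, for the transcription factor TBXT by 7.97 and for the matrix protein TGFBI by 7.85, and by at least 7.93 for SRGN. HCC95 was higher for epithelial genes: KRT13 was at least 205-fold lower in H460, the adhesion molecule EPCAM at least 196-fold and KRT5, a keratin of basal cells, at least 178-fold. Of 20 basal and squamous genes, 19 were lower in H460 and 0 higher (19 adjusted over the list alone). Of 20 epithelial genes, 15 were lower and 4 higher. The 17 mesenchymal genes went both ways, with 7 higher in H460 and 10 lower. With median scaling 2351 genes were higher in H460 and 4262 lower. Each line had 1 array per vector, so the spread between cultures of a line was not measured.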

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

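All tests in this part were chosen after the results were seen. The LZTFL1 effect differed between H460 and HCC95 for 18 of the named genes in a limma fit with a term for that difference (adjusted p under 0.05, 1 residual degree of freedom). The values that follow are H460 minus HCC95 on the log2 scale. Genes lower in HCC95 arrays labelled LZTFL1, and in H460 less so, not at all or higher, were MMP10 (3.81), LCP1 (2.19), STOM (2.18), CHAC1 (2.32), IL1A (2.26), AMTN (2.19), TNC (2.08), CLDN1 (1.87), IGFBP3 (1.84), CDH2 (1.71), KRT14 (1.69), CDH11 (1.60), SNAI2 (1.52), MAL2 (1.27) and the MIR21 probe (1.76). Among those detected on both H460 arrays, MAL2 (0.67), STOM (0.50), TNC (0.38) and LCP1 (0.23) were higher in H460 with the LZTFL1 label. CLDN1 (-0.06), CDH11 (-0.12) and IGFBP3 (-0.18) were slightly lower there. Genes higher in HCC95 and less so in H460 were SPP1 (-1.42), PRDX4 (-1.31) and LGALS1 (-1.20). MMP10, IL1A, AMTN, CDH2, KRT14 and the MIR21 probe were detected on 0 H460 arrays, and CHAC1 and SNAI2 on the LZTFL1 one only, so for these 8 genes H460 could not have shown a fall.

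The first pattern is that 8 of 19 TGF-β targets fell in the arrays labelled TGFβ. Under each of the other 4 normalizations at least 5 members fell and 0 rose. That is the smallest number the test allowed, it came without background correction, and the limit was written after the results were seen. With median scaling 746 of the 867 genes called in the TGFβ fit were lower, so falls were favoured there. The fall held under these settings, but all of them start from the same arrays, so a lower signal of these arrays is not excluded. An exchange of treated and untreated labels in both vectors and a true fall of these targets in treated cells were not tested, and both stay open.

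The second pattern is that the LZTFL1 probe was not clearly higher in any array labelled LZTFL1, with a difference in H460 within the spread between probes (0.199). An exchange of vector labels in 1 of the HCC95 contexts is argued against by the correlation of 0.488 between the differences of these contexts, which such an exchange would turn negative. A probe that lies outside the introduced sequence cannot be told apart from a vector that did not raise the transcript: the H460 difference of 0.0304 is what either would give, and the probe's position is not known here. An exchange in both contexts was not tested.

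The third pattern is that small nuclear RNAs were higher in the arrays labelled LZTFL1, with medians of 0.78 in untreated HCC95, 0.56 in HCC95 labelled TGFβ and 0.29 in H460. They were also higher by 0.56 in the GFP array labelled TGFβ than in the untreated one, and by 0.05 with LZTFL1. A better recovery of all short RNAs should raise small nucleolar RNAs as much. The excess over these was 0.60 and 0.40 in HCC95, with bootstrap intervals above 0, but 0.20 in H460, with an interval from -0.09 to 0.34, so that explanation cannot be told apart from a change in small nuclear RNAs. Without the near-identical U1 genes the median lay at percentiles 99.98, 98.2 and 96.9 of random lists not matched on brightness, the last just under the limit set, so shared probes are not excluded for H460.

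For the 1 gene of the shared LZTFL1 fit, the 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1 gene and the highest of the others 0, so 1 of the 10 splits called as many. Only 4 of the splits part all 3 pairs as the real one does, and the other 6 part 1 pair. At an unadjusted p under 0.05 the real split had 1394 genes and another split had 1601. That other split kept the HCC95 vector labels and exchanged only those of H460. The count of 1394 therefore does not show an effect shared by both lines.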

How the results depend on the processing

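The counts of genes higher and lower by 2-fold depend on the processing in size, and in some comparisons the larger of the pair changes. Main counts were 61 and 86, 52 and 105, 11 and 10, 87 and 32, 132 and 76 and then 96 and 84, for LZTFL1 in untreated HCC95, in HCC95 labelled TGFβ and in H460, TGFβ with GFP and with LZTFL1, and the difference between vectors. In that order they were 4 and 24, 5 and 34, 1 and 0, 22 and 8, 38 and 11 and then 3 and 5 without background correction, where compression towards 0 is built in. They were 20 and 42, 18 and 58, 1 and 0, 42 and 14, 58 and 32 and then 24 and 21 with an offset of 50, which compresses in the same way. With median scaling they were 30 and 209, 54 and 95, 16 and 3, 26 and 242, 82 and 144 and then 296 and 33. With the authors' processed values they were 176 and 197, 129 and 196, 38 and 103, 190 and 66, 316 and 162 and then 257 and 244. Without the detection filter they were 127 and 146, 167 and 222, 110 and 104, 148 and 88, 222 and 178 and then 406 and 421, because 37256 features were counted. At 1.5-fold they were 620 and 635, 610 and 660, 180 and 251, 602 and 415, 869 and 625 and then 812 and 716. With detection on every array, H460 had 6 and 5. With median scaling the median of all genes was -0.15, 0.06, 0.13, -0.28, -0.05 and 0.19 in these comparisons, and the cause was not tested. The shared LZTFL1 fit called 1 gene, SCNN1A, and it called 0 without background correction, with an offset of 50, with the processed values, with averaged probes, without the trend and without the context term. It called 79 with median scaling and 17 without the detection filter. With each pair left out in turn it called from 0 to 972 genes, the latter without H460. The TGFβ fit called 447 in place of 786 genes without background correction, 443 with averaged probes, 55 without the trend and 9 without the vector term; the causes were not tested. Of its 786 genes, 447 were shared with the count without background correction and 468 with the 867 of median scaling. The LZTFL1 fit without H460, recounted after its result was seen, called 522 in place of 972 without background correction, 400 with median scaling, 535 with averaged probes, 86 without the trend and 5 without the treatment term. The 7345 genes of the cell line difference stayed within 1.5 times under every setting run. Lists called by camera fell from 8 in the TGFβ fit and 2 in the shared LZTFL1 fit to 0 with an estimated correlation. That test has 1 or 2 residual degrees of freedom, too few to tell whether a list moved. The shared LZTFL1 fit called 6 lists with median scaling, and from 2 to 6 with a pair left out. The LZTFL1 probe's difference in untreated HCC95 was -1.09 with the processed values, -0.21 without background correction and -0.38 with an offset of 50, against -0.68; the LZTFL1 value was not detected, so these are differences from background, and with the detection floor it was at least -0.41. With median scaling, the GFP pair's median for the hypoxia list turned from 0.19 to -0.19 and for the unfolded protein list from 0.17 to -0.17. The difference for GSTTP2 turned from 1.49 to -0.25 with averaged probes. Among other values, 499 list medians moved by less than their spread and 113 by more, and 3020 values of named genes kept within it or on their side of the threshold, 503 moved by more, 23 lost the threshold and 15 gained it. Slide as a block and each LZTFL1 probe in turn were not run, the first because slides were not used here and the other because 1 probe carries the name. Leaving out genes found in several lists changed nothing, because no gene lies in more than 1 list. No paired analysis was possible because the groups share only 1 replicate number, beyond the context and vector terms of the fits. Signal over background limits all of this, since between 29.9% and 34.7% of probes were detected on each array.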

Other observations

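The test in this part was chosen after the results were seen. The genes in it were picked after CYP1A1 had been seen. With the TGFβ label in HCC95, CYP1A1, a cytochrome P450 that is a textbook target of the aryl hydrocarbon receptor, rose by 2.07 (SE 0.217, adjusted p = 1.92e-07), CYP1B1 2.83-fold (SE 0.124, adjusted p = 1.93e-09) and ALDH3A1, an aldehyde dehydrogenase, by 0.82 (adjusted p = 3.74e-06). CYP1A1 also fell with the LZTFL1 label, by 1.76 in the 4 HCC95 arrays (adjusted p = 4.01e-06), whereas CYP1B1 differed by 0.17 with that label and did not pass (adjusted p = 0.448). CYP1A1 was not detected on the untreated array labelled LZTFL1, so its fitted rise and fall both use a value at background. Where both arrays detected it, CYP1A1 rose by 2.26 with GFP and differed by -1.95 between the arrays labelled TGFβ.

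Activity of the aryl hydrocarbon receptor may lie behind CYP1A1 and CYP1B1, as a hypothesis. A list of 6 of its targets was written after CYP1A1 had been seen, and 5 were measured. A first version of the test counted CYP1A1 and CYP1B1 themselves, which made it partly circular, so it was restated on the other 3. Of these, 2 rose, ALDH3A1 and NQO1 (0.38, adjusted p = 0.0402), while TIPARP differed by 0.29 (adjusted p = 0.202). NQO1 is also in the NRF2 list, of which 7 of 13 members rose, so these values do not separate the receptor from NRF2.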
